A study of Mus musculus with 31 samples.

How the data were processed

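Regulatory T cells (Tregs), per the labels' protocols live CD45+ CD3+ CD4+ CD8- CD25+ cells sorted by flow cytometry without a FOXP3 gate, were profiled by RNA sequencing in 31 libraries of mice on the FVB/N background. The tumor-bearing mice were K14cre;Cdh1F/F;Trp53F/F (KEP), in which a keratin 14 promoter drives deletion of E-cadherin and p53 in epithelium and mammary tumors arise; they carried tumors of 225 mm2. Their wild-type (WT) littermates had the same floxed alleles without the Cre transgene. Each KEP library came from 1 mouse and each WT library from a pool of 3 mice, and 4500 to 70000 cells were sorted per library. Tumors were digested with collagenase A and lungs with Liberase, per the labels' protocols, which state no digestion for the other tissues.

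The deposited file held raw read counts per gene, whole numbers for 24594 Ensembl genes with symbols, of which 172 were 0 in every library. Per the labels' protocols the libraries were made with a stranded TruSeq mRNA kit from RNA of high integrity and sequenced as 65-base single reads. Per the submitters' processing notes the authors used TopHat2 2.1.0, TopHat and HTSeq with the GRCm38 mouse genome to obtain these counts; the notes do not say which step each tool served, which annotation release was used or whether counting used the strand. Coordinates are GRCm38 positions from a GENCODE M21 annotation whose build matches that assembly, and 24270 gene identifiers of the file were found in it. Named genes that overlap another gene on the genome are given as uncertain, since the strand setting is not stated.

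Depth ran from 8154765 to 15258958 counts per library. CPM, counts scaled to the library total, were computed with TMM factors; error terms are standard deviations (SD) over libraries for levels and standard errors (SE) for log2 fold changes. No share of counts from a single library is given with an interval, since the spread between libraries was larger than counting error: pairs of replicates differed by 4.67 to 188.9 chi-square per degree of freedom, and no pair was a duplicate.

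The tests were fixed before the data were examined. The main test was the quasi-likelihood F test of edgeR 4.0.16 (R 4.3.3) with robust dispersion on all 31 libraries in a single fit with 1 mean per group of tissue and genotype (10 groups), TMM factors and the filter of filterByExpr at a minimum count of 10, which left 15202 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and adjusted p-values below come from this test unless another is named. Gene lists (29, with 436 symbols, of which 4 were not in the file) were fixed before the data were examined, some for cell states of T cells and the others for markers of cells that the gate could let through. They were tested by camera of limma 3.58.1 with an inter-gene correlation of 0.01, adjusted over 145 tests, and again with the correlation estimated from the data. Members were also counted after adjustment over the list alone. The genes named in the text were fixed by a rule: per KEP against WT comparison the 10 higher and 10 lower genes with the smallest p among called genes at a change of at least 2-fold, a mean of at least 5 CPM and no overlap between the groups, leaving out marker genes of other cell types, immunoglobulin and receptor segments and unnamed genes; 6 each way for the comparisons of tissues; up to 4 called members of each list, or its member with the smallest p; and Foxp3, Il2ra, Ctla4, Ikzf2, Cd4, Cd3e, Cd8a, Trp53 and Cdh1. Genes outside the rule are named as such where they appear.

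Title dates recur across tissues within a genotype and never across genotypes. For KEP mice, libraries of blood, spleen, lung and lymph node with the same date deviated together from their group means in all 18 pairs (median correlation across genes 0.265, lowest 0.188); for WT pools 7 of 18 pairs exceeded 0.1 (median 0.09), and pairs with a mammary gland or tumor library were near 0 (medians -0.003). Since the labels share a date across the tissues, the date was treated as the pairing of libraries between tissues, and a fit with the date as a block is given beside the comparisons between tissues where it moved the result. Comparisons of KEP with WT cannot hold a fixed date term, because no date had both genotypes, so any effect of the title date cannot be told apart from the genotype. For them the date entered only as a random term in limma-voom.

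Alternatives were RLE and upper-quartile factors, no filter and a minimum count of 50, the number of sorted cells as a covariate, only the libraries compared, DESeq2 1.42.0, limma-voom with and without the date as a random block, a minimum change of 2-fold, and leaving out each library. Chosen after the data were seen were a correction for GC content and transcript length (smooth trends with 5 degrees of freedom per library), the fit of the 24 libraries of blood, spleen, lung and lymph node alone, scaling to 10 pan-T genes, and WT mammary gland replicate 2 as the only control. On simulated counts with 200 changed genes per comparison and 15008 genes, edgeR recovered 65.7% of genes changed 2-fold between tumor and mammary gland, 70.1% in lymph node, 59.7% in spleen, 61.2% in lung and 67.2% in blood, with at most 21 false calls, those of the tumor comparison. The changed genes were drawn from those with a mean of at least 5 CPM, and each gene had the same dispersion in every group. These rates therefore do not cover genes of lower level. Nor do they cover the larger spread of real tumor and mammary gland libraries. For the test of differing effects among tissues, date effects with an SD of 0.3 on the log2 scale were added to simulated counts of 12785 genes. With them the fit without a block recovered 1.6% of genes changed 2-fold and the fit with the date as a block 54.3%. Without added date effects the fit of all 31 libraries without a block recovered 54.1%. The size of the added effects was not matched to the data, so the loss depends on that choice. A planted list was called in each of the 5 comparisons, and 0 of the 29 fixed lists were called on the simulated counts. The simulated genes varied independently of each other. This therefore does not test the list calls on the real counts, where members of a list vary together. No sequence variants were analysed here. The results of some genes that the rule selects are not reported here.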

Results

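RNA was measured in 31 libraries of sorted regulatory T cells from tumor-bearing KEP mice and their WT littermates. Blood, spleen, lung and lymph node gave 3 libraries per genotype; the KEP lymph nodes were those draining the tumor. Tumors gave 3 KEP libraries, and the healthy mammary gland, their counterpart, gave 4 WT libraries. Total counts per library ran from 9476533 to 11609950 in KEP blood, 11465657 to 12726090 in KEP spleen, 11596876 to 13241413 in KEP lung, 11207373 to 14044495 in KEP lymph node and 10727207 to 11502183 in tumor. They ran from 8838218 to 10024307 in WT blood, 10211727 to 12864755 in WT spleen, 8154765 to 9737722 in WT lung, 8446510 to 10528692 in WT lymph node and 12328950 to 15258958 in WT mammary gland. Levels below are CPM as mean ± SD over these libraries (n = 3 per group, n = 4 for WT mammary gland), given KEP first, and log2 fold changes are KEP against WT with their SE. Genomic positions are on GRCm38.

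The deleted genes come first. Trp53, the gene of the tumor suppressor p53 (chromosome 11, 69580359 to 69591873), was measured in every library, at 54.4 to 154.8 CPM in the tumor group and 137.1 to 234.9 CPM in mammary gland. It stood at 123 ± 10.2 against 170 ± 4.46 CPM in blood, 174 ± 6.03 against 226 ± 8.69 in spleen, 197 ± 17.5 against 251 ± 11.3 in lung and 202 ± 6.68 against 220 ± 17.8 in lymph node. Of these 4 differences none was called in the fit of all libraries; with the 24 libraries of these tissues alone, a fit chosen after the data were seen, Trp53 was lower in spleen (-0.38, adjusted p = 0.00414), lung (-0.36, adjusted p = 0.00252) and blood (-0.49, adjusted p = 0.000186). Cdh1, the gene of E-cadherin (chromosome 8, 106603351 to 106670246), stood at 329 to 555 CPM in WT mammary gland and at 5.99, 9.61 and 225.6 CPM in the 3 tumor libraries, while the mean of every other group was at most 5.51 CPM. The deletion acts in epithelium that expresses keratin 14, so neither gene checks the genotype labels of sorted T cells. Between tumor and mammary gland Trp53 fell by 0.94 on the log2 scale (adjusted p = 0.000515) and the value for Cdh1 was -2.56 (adjusted p = 0.00496), while with the libraries of this comparison alone neither was called (adjusted p = 0.16 and 0.168). Cd8a, which the sort excluded, had a mean of at most 2.41 CPM in any group.

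The share of T cell transcripts differed among groups. The summed CPM of 10 pan-T genes, such as Cd3e and Lck, was set against its mean in WT spleen. It was 91.5% to 102% of that level in the group means of blood, spleen, lung and lymph node. It was 67.2 ± 37.4% in tumor (32.7% to 107%) and 12 ± 14.4% in WT mammary gland (2.95% to 33.4%, the highest being replicate 2). Milk protein transcripts took 0.536% to 3.44% of the counts in WT mammary gland, and 0.501% in KEP tumor replicate 3, the tumor library with the lowest pan-T level, against 0.00192% and 0.000278% in the other tumor libraries.

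**Figure D1:**
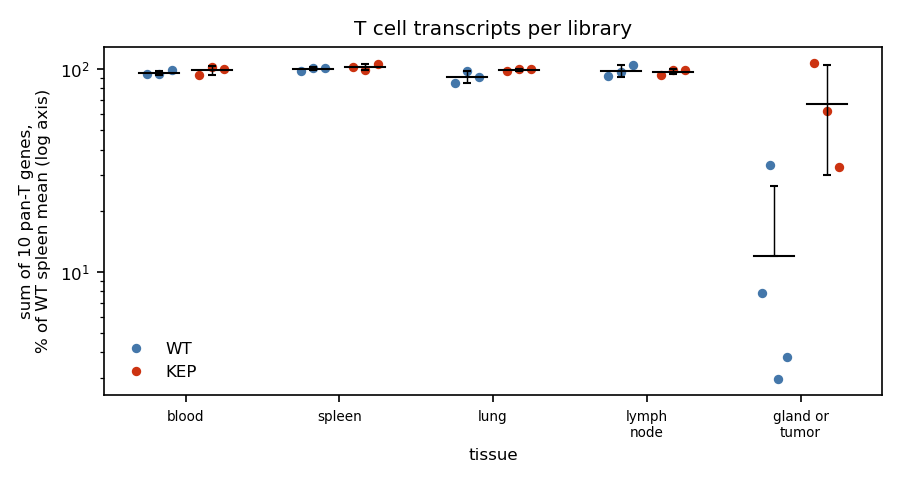
Summed CPM of 10 pan-T genes per library, as a percentage of the WT spleen mean on a log axis, by tissue and genotype; points are libraries, long bars are means and whiskers are SD, with the lower whisker left out where the SD exceeds the mean. WT mammary gland spans 2.95% to 33.4% and tumor 32.7% to 107%, while the group means of the 4 other tissues lie between 91.5% and 102%.

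Tumors were compared with healthy mammary gland to ask how Tregs in the tumor differ from those in the tissue it arose in. The labels state a collagenase digestion for tumors and none for mammary gland, which this comparison does not separate from the tissue. Transcripts of Treg identity, activation and suppression were higher in tumor. Foxp3, the lineage-defining transcription factor of Tregs (chromosome X, 7579676 to 7595243), stood at 973 ± 585 against 140 ± 187 CPM (log2 fold change 2.80, SE 0.59, adjusted p = 0.000407). With the libraries of this comparison alone Foxp3 was not called, as given below. Gzmb, the cytotoxic protease granzyme B, stood at 387 ± 225 against 6.23 ± 6.4 CPM (5.99, SE 0.54, adjusted p = 1.01e-08). Havcr2, the inhibitory receptor TIM-3, stood at 63.5 ± 27.6 against 3.5 ± 3.06 CPM (4.21, SE 0.39), and Ccr8, a chemokine receptor of tissue Tregs, at 174 ± 114 against 9.69 ± 13.7 CPM (4.19, SE 0.62). WT mammary gland replicate 2 carried much of the control means. Without it the log2 fold changes were 4.37 for Foxp3, 6.99 for Gzmb, 5.02 for Havcr2 and 5.95 for Ccr8. Against it alone they were 1.24, 4.65, 3.00 and 2.54, given as effect sizes only because that control was 1 library. Epithelial transcripts were lower, such as Krt19, an epithelial keratin, at 52.5 ± 53.2 against 742 ± 66.5 CPM, as was Myh11, the gene of a smooth muscle myosin, at 4.71 ± 4.23 against 790 ± 201 CPM.

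The 10 higher genes with the smallest p were led by Cdkn2a, which encodes cell cycle inhibitors (chromosome 4, 89274471 to 89294653), at 82.9 ± 32 against 0.711 ± 0.201 CPM (6.84, SE 0.44, adjusted p = 8.71e-11). They also held Pglyrp1, a peptidoglycan recognition protein (3.43), Hpse, heparanase (3.77), the glycolytic enzyme Pgk1 (2.09), Arl5a, a small GTPase of the ARF family (2.82), Rnf157 (4.46), Apaf1, the scaffold of the apoptosome (1.35) and Mov10 (2.06); Capza1 (1.39), which overlaps St7l, is uncertain. The 10 lower genes included Plekha6 (-4.14), Myh11 (-7.39), Mapkbp1 (-2.28), Hsdl2 (-2.42), the collagen receptor Ddr1 (-2.07), the lipase Pnpla2 (-1.67) and the transcription factor Mafk (-1.53). Gcc1 (-2.19), which overlaps Arf5, and Sh3bp5 (-2.67), which overlaps Capn7, are uncertain.

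In the same comparison 13 of 15 macrophage and monocyte genes rose. Whether RNA of such cells raised members of the T cell lists was not tested. Among T cell lists, all 18 Treg activation genes rose, Cd80 by 4.65, Id2 by 3.04, Prdm1, the gene of Blimp-1, by 2.37 and Cd44 by 2.33 on the log2 scale (18 adjusted over the list alone). Of 13 Treg identity genes 11 rose (11 adjusted over the list alone), including Il2ra, the high-affinity IL-2 receptor chain (3.25), Tnfrsf18 (3.26), Ikzf4 (1.77) and Capg (2.12). Of 18 genes of inhibitory receptors and suppressive mediators 13 rose (14 adjusted over the list alone), among them Lgals1 (2.99) and Fgl2 (1.91). Of 24 homing receptors 18 rose (20 higher and 1 lower adjusted over the list alone), such as the chemokine receptors Ccr2 (3.95) and Ccr1 (4.89); Cx3cr1 (5.48), which overlaps other genes, is uncertain. Of 16 tissue Treg genes 12 rose and 1 fell (14 and 1 adjusted over the list alone), with Batf at 2.83 and Nfil3 at 1.23. Of 15 conventional effector genes 4 rose and 1 fell, with the same counts adjusted over the list alone; the cytokine gene Csf2 rose by 3.22 on the log2 scale. Of 14 resting and central genes 4 rose, among them the IL-7 receptor gene Il7r (3.14), and 4 fell, among them Bcl2 (-1.21); adjusted over the list alone 6 rose and 5 fell.

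Of 30 type I interferon genes 25 rose (26 adjusted over the list alone), such as Oas3 (4.35), Zbp1 (3.34) and Oas1a (3.75). Of 20 interferon gamma genes 16 rose and 1 fell (17 and 2 adjusted over the list alone), with Cd274, the gene of PD-L1, at 2.32; Gbp7 and Gbp3 overlap Gbp5 and are uncertain. Of 15 NF-kB genes 12 rose (13 adjusted over the list alone), Tnfrsf9, which encodes 4-1BB, by 5.01 and Traf1 by 2.97 on the log2 scale. Of 25 glycolysis and hypoxia genes 19 rose, with Hif1a at 2.01 and Pkm at 1.51, and 2 fell, among them Pfkfb3 (-1.43), with the same counts adjusted over the list alone. Of 15 IL-2 and STAT5 genes 10 rose and 3 fell, among them Socs3, an inhibitor of cytokine signalling (-1.75), with the same counts adjusted over the list alone. Of 16 early T cell receptor response genes 8 rose, such as Rel (2.21), and 4 fell, such as Egr1 (-2.13) and Egr2 (-2.90); the counts adjusted over the list alone were the same. Of 23 dissociation stress genes 2 rose and 10 fell, such as Ier2 (-1.21) and Btg2 (-0.69), with the same counts adjusted over the list alone. Of 19 cholesterol and lipid genes 8 rose, such as Dhcr7 (0.86), and 4 fell, such as Fasn (-1.51) and Cd36 (-3.80); 9 rose and 4 fell adjusted over the list alone, and the median, mean and test of the list differed in sign. Of 19 oxidative phosphorylation genes 2 rose, such as Sdhb (0.46), and 5 fell, such as Atp5a1 (-0.42), with the same counts adjusted over the list alone. Of 30 proliferation genes 1 was called, Tk1 (1.35), which overlaps Afmid, and 0 were called adjusted over the list alone. The direction of this list depended on the control and the scaling. Its median log2 fold change was 0.46, against 2.47 with WT mammary gland replicate 2, 1 library, as the only control. With pan-T scaling the median was -2.89 and all 30 genes were called lower. As lists, the last 5 of this paragraph did not pass, the smallest adjusted p being 0.0762 for proliferation.

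Markers of several other cells also differed. Of 15 macrophage and monocyte genes 13 rose, with C1qc at 191 ± 194 against 4.87 ± 3.29 CPM, Itgam at 113 ± 113 against 3.21 ± 1.94 CPM and Fcgr3 at 57.4 ± 50 against 1.36 ± 0.66 CPM. Of 8 dendritic cell genes 7 rose, with Cd74, the invariant chain, at 1174 ± 987 against 205 ± 59 CPM and Xcr1 at 7.75 ± 3.97 against 0.712 ± 0.681 CPM. Of 9 CD8 T and NK cell genes 6 rose, such as Nkg7 (3.58) and Ccl5 (4.42); Prf1 (2.64) also belongs to the list of suppressive mediators. Of 10 neutrophil genes 5 rose, such as Mmp9 (6.60), and 1 fell, Ltf (-3.43), a gene of neutrophils and of milk. All 7 mast cell and basophil genes fell, such as Gata2 (-2.47) and Kit (-2.39), as did 11 of 13 epithelial genes (12 adjusted over the list alone), such as Cldn4 (-4.69) and Elf5 (-4.57). Of 12 milk and fat cell genes 9 fell, such as Fabp4 (-4.37). Of 14 stroma and endothelium genes 5 rose, such as Col1a1, a collagen of fibroblasts (3.38), and 6 fell, such as Pecam1 (-1.66). Of 11 B cell genes 2 rose, among them Ighm (2.09), and 2 fell, among them Ebf1 (-1.56). Of 7 plasma cell genes none was called, the smallest p being that of Derl3 (1.5 ± 1.55 against 2.91 ± 1.39 CPM). Of 5 lung epithelium genes 1 rose, Napsa (2.78), and 1 fell, Ager (-0.75), which was not called adjusted over the list alone. Of 13 red cell and platelet genes 2 rose, Pf4 (3.74) and Ppbp (4.00), and 3 fell, such as Hba-a1 (-2.28). Adjusted over the list alone, the other lists of this paragraph gave the same counts. For the B cell, stroma and lung epithelium lists the median, mean and test differed in sign.

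In this comparison 8064 of 15202 genes were called, 3580 higher and 4484 lower, of which 1916 and 2777 changed at least 2-fold. In 5556 of the called genes the KEP and WT libraries did not overlap. With the preset correlation 16 of 29 lists passed: Treg identity, activation, inhibitory and suppressive, tissue Treg, homing, type I interferon, interferon gamma, NF-kB, IL-2 and STAT5, glycolysis, macrophage, dendritic cell, and CD8 and NK lists as higher, and mast cell, epithelium and milk lists as lower. None held when the correlation was estimated (each adjusted p = 0.865 with an estimated correlation). Scaling the libraries to the 10 pan-T genes moved the median of all genes from -0.10 to -3.43 on the log2 scale. It gave 126 genes higher and 14006 lower. With that scaling 4 of 13 identity genes were called higher and 6 lower, and 8 of 18 activation genes higher and 1 lower. The other T cell lists that had passed held more lower than higher genes. Suppressive mediators had 5 higher and 9 lower, tissue Treg genes 3 and 6, and homing receptors 5 and 6. Type I interferon genes had 3 higher and 18 lower, interferon gamma genes 0 and 18, and NF-kB genes 2 and 11. IL-2 and STAT5 genes had 3 higher and 12 lower, and glycolysis genes 1 and 24. Gzmb stayed higher at 3.15 and Foxp3 stood at 0.55 (adjusted p = 0.0546). Of the named genes 40 changed sign, some called lower, such as Prdm1, Hif1a and Pgk1, and others not called, such as Batf and Col1a1. With the libraries of this comparison alone the count was 3667 and Foxp3 was not called (2.91, adjusted p = 0.0879). Pairs of replicates differed by 94.5 to 188.9 chi-square per degree of freedom in tumor and 22.7 to 110.1 in mammary gland. In the other groups they differed by at most 17.5. The fit of all libraries shares its spread over the groups. It can therefore understate the SE and p-values of comparisons with tumor or mammary gland libraries.

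**Figure D2:**
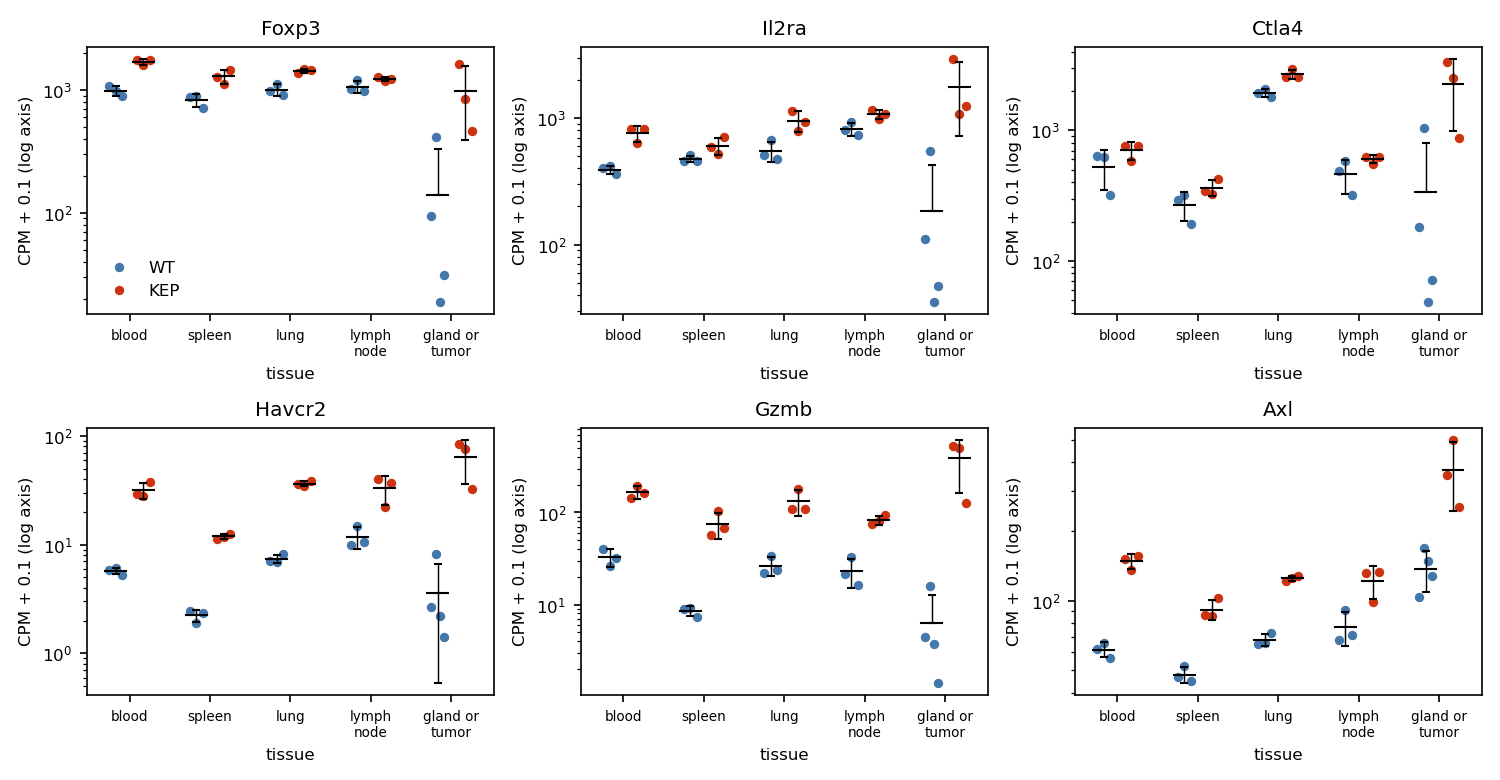
CPM plus 0.1 on a log axis of Foxp3, Il2ra, Ctla4, Havcr2, Gzmb and Axl per library, by tissue and genotype; points are libraries, long bars are means and whiskers are SD, with the lower whisker left out where the SD exceeds the mean. Havcr2 stood at 31.6 ± 5.31 CPM in KEP blood against 5.63 ± 0.42 CPM in WT blood.

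The lymph nodes draining the tumor were compared with lymph nodes of WT mice. The genes called were Clgn, an endoplasmic reticulum chaperone, at 5.61 ± 2.97 against 0.366 ± 0.184 CPM (3.93, SE 0.63, adjusted p = 0.0143), and Cr1l, a complement regulator, at 134.2 ± 0.418 against 75.7 ± 1.02 CPM (0.83, SE 0.11, adjusted p = 0.00218); they were named after their values were seen. Proliferation genes stood higher together: all 30 had a log2 fold change above 0 (median 1.70), and 15 passed adjusted over the list alone, although none did over all genes. Ccnb2, a cyclin of mitosis, stood at 19.3 ± 8.97 against 5.45 ± 2.07 CPM (1.84). The suppressive list had 2 genes higher adjusted over the list alone, and Havcr2 stood at 32.9 ± 9.7 against 11.6 ± 2.63 CPM (adjusted p = 0.258). Foxp3 stood at 1226 ± 46.2 against 1066 ± 125 CPM.

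With the preset correlation 9 lists passed in lymph node: proliferation (adjusted p = 4.22e-17), suppressive mediators, Treg activation, IL-2 and STAT5, glycolysis, oxidative phosphorylation and B cell genes as higher, and conventional effector and red cell genes as lower. With the correlation estimated none did (adjusted p = 0.932 with an estimated correlation for Treg activation and 0.865 for the other 8). With the GC and length correction oxidative phosphorylation did not pass (adjusted p = 0.088), nor did conventional effector genes with RLE factors (adjusted p = 0.0651). Macrophage genes passed as higher with either (adjusted p = 0.0317 and 0.0426). In the 24 libraries of the 4 tissues the suppressive list passed with an estimated correlation (adjusted p = 0.033), and Havcr2 (1.51, adjusted p = 4.12e-05), Ccnb2 (1.85, adjusted p = 0.0488) and Socs3 (0.72, adjusted p = 0.0153) were called. Members with the smallest p in other lists were not called, such as Igfbp4 (187.5 ± 32.7 against 47.1 ± 31 CPM) and the NK receptor gene Klrb1c (8.38 ± 2.04 against 27.1 ± 6.61 CPM). The edgeR test called 2 genes, both higher, with 874 at an unadjusted p under 0.05; DESeq2 called 37 (14 higher and 23 lower), limma-voom 1, the libraries of this comparison alone 193 (117 and 76) and the 24 libraries 143 (85 and 58). Leaving out WT replicate 1 or 3 or KEP replicate 1 gave 1 gene, leaving out WT replicate 2 or KEP replicate 2 gave 5, and leaving out KEP replicate 3 gave 4. The mammary gland and tumor libraries vary more than the others and widen the spread shared in the fit of all libraries.

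In spleen, 66 of the 68 genes called between KEP and WT Tregs were higher in KEP mice, and 2 of 18 suppressive mediators were among the higher ones. Gzmb (chromosome 14, 56258856 to 56262260) stood at 75.7 ± 23.9 against 8.42 ± 1.02 CPM (3.17, SE 0.55, adjusted p = 0.00514) and Havcr2 (chromosome 11, 46454935 to 46481255) at 11.8 ± 0.635 against 2.13 ± 0.291 CPM (2.47, SE 0.44, adjusted p = 0.00586). Socs3 stood at 418 ± 61.8 against 204 ± 32.6 CPM (1.04, SE 0.17, adjusted p = 0.00238), and Itga2, a collagen-binding integrin chain, at 24.1 ± 0.176 against 8.83 ± 1.7 CPM (1.44, SE 0.24, adjusted p = 0.00308). The other leading genes were Plekha6 (2.05), Plxdc1 (1.87), S100a6, a calcium-binding protein (1.51), Gcnt1, an enzyme that branches O-glycans (1.47), Arl5a (1.32), Acvrl1, a receptor of the TGF-beta family (1.29) and Atrnl1 (1.14); Fam129b (1.46), which overlaps Lrsam1, is uncertain. Foxp3 stood at 1286 ± 167 against 828 ± 97.2 CPM (0.64, SE 0.62, adjusted p = 0.91); in the 24 libraries of the 4 tissues it was called (0.63, adjusted p = 0.000581), as was the integrin gene Itgae (2.08, adjusted p = 6.07e-08).

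Of 18 suppressive mediators 2 rose in spleen (3 adjusted over the list alone), and of 16 tissue Treg genes 1 rose, Nfil3 (0.98; 3 adjusted over the list alone). Of 18 Treg activation genes 0 were called over all genes and 3 adjusted over the list alone, with 16 above 0. Of 15 IL-2 and STAT5 genes 2 rose, Socs3 and Gzmb (4 adjusted over the list alone). All 30 proliferation genes were above 0 (median 1.88), none called over all genes and 8 adjusted over the list alone; Mki67, a marker of cycling cells, stood at 102 ± 56.3 against 21.4 ± 4.15 CPM. Of 24 homing receptors 4 were higher adjusted over the list alone, and Ccr1 stood at 3.86 ± 0.784 against 0.405 ± 0.171 CPM. Among markers of other cells, 7 of 10 neutrophil genes were higher adjusted over the list alone, S100a9 at 12.5 ± 19.7 CPM against 0 in WT spleen, and 1 of 15 macrophage genes, Itgam, at 10.6 ± 4.5 against 1.6 ± 1.15 CPM. All 13 red cell and platelet genes were above 0.

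In spleen 68 genes were called, 66 higher and 2 lower, with 1214 at an unadjusted p under 0.05, and the libraries did not overlap in any of the 68. With the preset correlation 10 lists passed: activation, suppressive, tissue Treg, homing, proliferation, IL-2 and STAT5, macrophage, neutrophil and red cell genes as higher, and CD8 and NK genes as lower. None did with the correlation estimated (adjusted p = 0.887 with an estimated correlation for homing receptors and 0.865 for the others). In the 24 libraries 5 of these 10 passed with an estimated correlation: activation, suppressive, homing and IL-2 and STAT5 genes (each adjusted p = 0.033), and tissue Treg genes (adjusted p = 0.0488). DESeq2 called 174 genes (159 higher and 15 lower), the 24 libraries 546 (423 and 123) and the spleen libraries alone 589 (455 and 134). Leaving out 1 library of spleen gave 25 (without KEP replicate 3), 26, 28 and 31 (without WT replicates 2, 1 and 3), 36 (without KEP replicate 1) and 63. Without WT replicate 2 Havcr2 was not called (2.37, adjusted p = 0.0624), nor was Gzmb without WT replicate 3 (3.08, adjusted p = 0.0502).

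In lung, the site to which breast tumors often spread, KEP Tregs again carried more Havcr2, at 36.1 ± 1.88 against 7.27 ± 0.653 CPM (2.31, SE 0.41, adjusted p = 0.0044), and more Gzmb, at 133 ± 41.3 against 26.2 ± 6.14 CPM (2.35, SE 0.52, adjusted p = 0.0167). Prdm1 stood at 157 ± 6.52 against 75.7 ± 12.3 CPM (1.05) and Fgl2 at 248 ± 47.2 against 109 ± 18.1 CPM (1.19). Trp73, a relative of p53 (chromosome 4, 154056253 to 154140208), stood at 15.9 ± 0.496 against 3.82 ± 1.21 CPM (2.05). Klf2, a transcription factor of resting T cells, was lower, at 164 ± 21.2 against 302 ± 10.8 CPM (-0.88, adjusted p = 0.038). The other leading higher genes were Naprt1 (1.58), Ttll11 (1.57), Arl5a (1.43), Gcnt1 (1.20), Snx9, a sorting nexin of endocytosis (1.20), Atrnl1 (1.03) and Sypl (1.01). The leading lower genes were Slc22a4, an organic cation transporter (-2.49), Dtx4 (-1.43), Csf2ra, a GM-CSF receptor chain (-1.34), Gpc1, glypican 1 (-1.17), Pou6f1 (-1.15), Zfp827 (-1.14), Tdrp (-1.08), Ppan, a ribosome biogenesis factor (-1.02), the snoRNA host gene Snhg12 (-1.01) and Rps2, a ribosomal protein (-1.01). Foxp3 stood at 1432 ± 49.3 against 1006 ± 109 CPM (0.51, adjusted p = 0.728), and in the 24 libraries it was called (0.50, adjusted p = 0.00223), as was Il2ra (0.78, adjusted p = 0.000727).

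Of 18 suppressive mediators 3 rose in lung, Havcr2, Gzmb and Fgl2 (4 adjusted over the list alone), and of 18 activation genes 1 rose, Prdm1, with all 18 above 0. Of 25 glycolysis and hypoxia genes 3 rose, Ndrg1 (1.10), Pgk1 (0.63) and Hif1a (0.67); 4 rose and 1 fell adjusted over the list alone. Of 15 NF-kB genes 2 rose, Map3k8 (0.79) and Bcl3 (1.01; 3 adjusted over the list alone), and 1 of 16 tissue Treg genes rose, Nfil3 (0.69). Of 14 resting and central genes 1 fell, Klf2 (2 adjusted over the list alone). All 30 proliferation genes were above 0 (median 1.64), none called over all genes and 13 adjusted over the list alone. Of 15 macrophage genes 1 fell, Fcgr3 (-2.66), and the median of the list was -0.86; adjusted over the list alone 4 fell and 1 rose.

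In lung 469 genes were called, 253 higher and 216 lower, with 2887 at an unadjusted p under 0.05; the libraries did not overlap in 467 of them. With the preset correlation 6 lists passed: activation, suppressive, tissue Treg and proliferation genes as higher, and resting and macrophage genes as lower; none did with it estimated (adjusted p = 0.886 with an estimated correlation for resting genes and 0.865 for the others), while in the 24 libraries activation and suppressive genes did (each adjusted p = 0.033). Resting genes did not pass with RLE factors (adjusted p = 0.0549), and with the GC and length correction NF-kB, IL-2 and STAT5, glycolysis and neutrophil genes passed as higher (adjusted p = 0.0228, 0.0443, 0.0028 and 0.0374). Lower genes were richer in GC than higher ones (median 55.9% against 45%, all genes 50.2%), and with a correction for GC and length 309 genes were called, Klf2 not among them (-0.64, adjusted p = 0.114), nor Csf2ra, Fgl2, Map3k8 and Hif1a. Without a filter on low counts 264 genes were called, of which 67.8% were higher against 53.9% in the main test. DESeq2 called 956 genes, the lung libraries alone 1599 and the 24 libraries 2550, and leaving out 1 lung library gave 40 (without KEP replicate 1), 166 (without KEP replicate 2), 102, 135 and 114 (without WT replicates 1, 2 and 3) and 413.

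In blood, Havcr2 stood at 31.6 ± 5.31 against 5.63 ± 0.418 CPM (2.49, SE 0.41, adjusted p = 0.00223) and Gzmb at 166 ± 25.9 against 32.6 ± 7.29 CPM (2.35, SE 0.51, adjusted p = 0.013). Axl, a receptor tyrosine kinase (chromosome 7, 25757273 to 25788705), stood at 148 ± 10.9 against 61.3 ± 4.57 CPM (1.27, SE 0.18, adjusted p = 0.000477), and Arl5a (chromosome 2, 52397951 to 52424901) at 962 ± 51.3 against 288 ± 43.2 CPM (1.74, SE 0.23, adjusted p = 0.000196). Of 14 genes of resting T cells 2 were lower: Tcf7, the gene of TCF-1, stood at 288 ± 163 against 806 ± 167 CPM (-1.48, adjusted p = 0.0479), and the repressor gene Bach2 at 21.4 ± 8.63 against 50.9 ± 12.8 CPM (-1.24, adjusted p = 0.0363). Neither was called with the number of sorted cells in the model, though the effects had not shrunk. Tcf7 then stood at -1.58 (adjusted p = 0.0708) and Bach2 at -1.32 (adjusted p = 0.0613). The other leading higher genes were Trp73 (2.21), Msrb3 (1.92), Snx9 (1.29), Sh3bgrl (1.26), the tetraspanin gene Cd81 (1.11), Acvrl1 (1.04) and Atrnl1 (1.03). The leading lower genes were Tdrp (-1.48), Dzip1 (-1.43), Parp8 (-1.38), Tbc1d4, a regulator of vesicle traffic (-1.34), Zfp827 (-1.28), Snhg12 (-1.18), Arhgap39 (-1.15), the tRNA-modifying enzymes Mettl1 (-1.13) and Adat1 (-1.05), and Bcl7a (-1.08). Foxp3 stood at 1691 ± 89.1 against 986 ± 93.7 CPM (0.78, adjusted p = 0.555), and in the 24 libraries it was called (0.76, adjusted p = 5.15e-05), as were Il2ra (0.93, adjusted p = 0.000124) and Ikzf2, the gene of Helios (0.93, adjusted p = 8.71e-05).

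Of 18 suppressive mediators 3 rose in blood, Havcr2, Gzmb and Fgl2 (1.22), with 3 adjusted over the list alone, and of 18 activation genes 1 rose, Prdm1 (1.09), with 1 adjusted over the list alone. Of 24 homing receptors 2 rose, among them Ccr1 (2.62); adjusted over the list alone 3 rose and 1 fell. Of 14 resting and central genes 2 fell (3 adjusted over the list alone). Of 15 IL-2 and STAT5 genes 2 rose, Socs3 (0.89) and Gzmb, and Myc fell (-0.88); adjusted over the list alone 3 rose and 2 fell. Of 25 glycolysis and hypoxia genes 2 rose, Bnip3 (1.07) and Hif1a (0.82), with the same count adjusted over the list alone. Among other lists, Bcl3 rose (1.17), and Tnf (-1.19), the cholesterol enzyme gene Sqle (-0.87) and the interferon gamma gene Iigp1 (-1.06) fell. Gbp7 (0.74), an interferon gamma gene that overlaps Gbp5, is uncertain. Of 30 proliferation genes 26 were above 0 (median 0.63), with 0 called over all genes or adjusted over the list alone. Of 9 CD8 T and NK cell genes 1 fell, Klrb1c, at 21.9 ± 16.2 against 74.6 ± 24.1 CPM (-1.77), and of 11 B cell genes 1 fell, Fcer2a, at 0.613 ± 0.837 against 5.32 ± 4.94 CPM.

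In blood 657 genes were called, 332 higher and 325 lower, with 2823 at an unadjusted p under 0.05; the libraries did not overlap in 643 of them. With the preset correlation 8 lists passed: activation, suppressive, tissue Treg and glycolysis genes as higher, and resting, dissociation stress, cholesterol and B cell genes as lower; none did with it estimated (adjusted p = 0.886 with an estimated correlation for resting genes and 0.865 for the others), while in the 24 libraries activation genes did (adjusted p = 0.0409). Dissociation stress genes did not pass with the GC and length correction (adjusted p = 0.127), nor B cell genes with RLE factors (adjusted p = 0.0549). The number of sorted cells as a covariate gave 293 genes, without Tcf7, Bach2, Prdm1, Ccr1, Tnf and Klrb1c among others, and no filter on low counts gave 382. DESeq2 called 1064 genes, the blood libraries alone 1688 and the 24 libraries 2591, and leaving out 1 blood library gave 155 (without KEP replicate 3), 162 (without KEP replicate 1), 356, 266 and 249 (without WT replicates 1, 2 and 3) and 489. For all comparisons of 3 libraries with 3, chance alone separates the libraries of 10% of genes.

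The same genes recurred across spleen, lung and blood. In all 3 tissues 33 genes were higher and 2 lower, chosen as called in each; beside the named Havcr2, Gzmb, Gcnt1, Arl5a, Trp73 and Snx9 the set held Clgn (6.30 in spleen, 3.23 in lung, 4.45 in blood), Dlk1, Itga2 (1.44, 1.09 and 1.01), Axl (0.94, 0.89 and 1.27) and Bid, a pro-apoptotic gene (0.62, 0.62 and 0.53). DESeq2 called 58 genes higher in all 3 and the 24 libraries 247, with all 33 among them. With the number of sorted cells in the model the count was 23, with 22 of the 33 among them. The set's median log2 fold change was 1.14 in spleen, 1.08 in lung and 1.06 in blood. In lymph node, where the set was not chosen, all 33 were above 0, with a median of 0.67. Lung and blood shared 143 higher genes where independent lists would share 5.53, and 118 lower genes against 4.62; spleen shared 42 higher genes with blood against 1.44 and 37 with lung against 1.1. The libraries of the tissues share title dates, so these overlaps are not taken as independent.

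**Figure D3:**
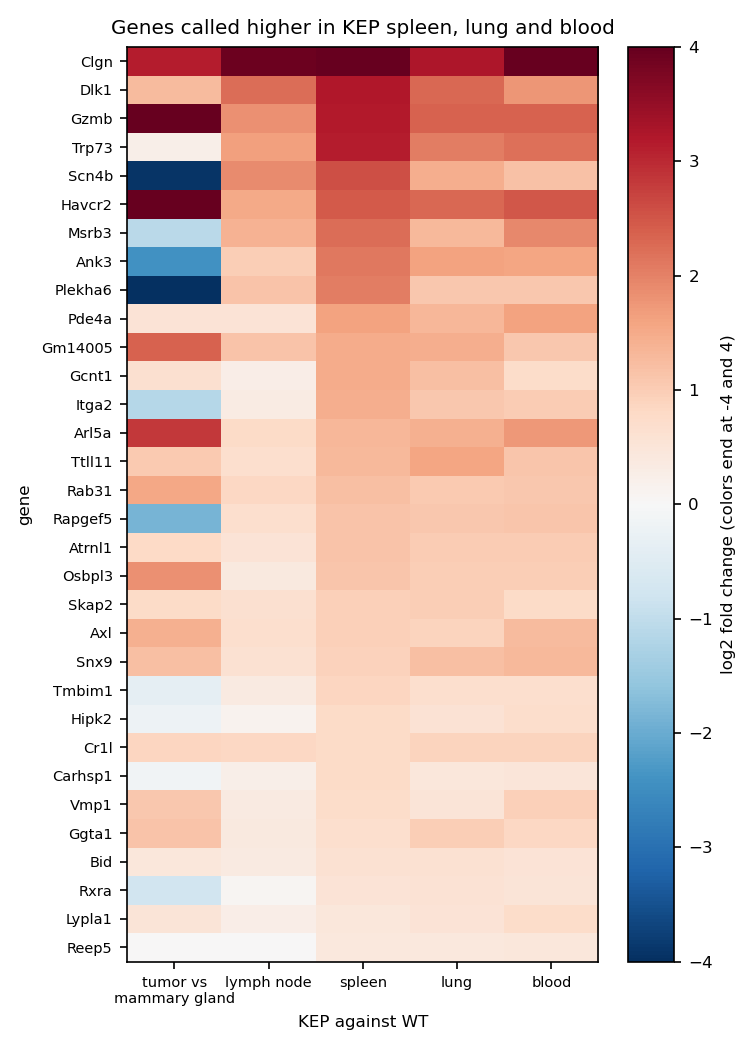
Log2 fold change, KEP against WT, of 32 of the 33 genes called higher in spleen, lung and blood, with genes as lines ordered by spleen and comparisons as columns; colors end at -4 and 4. The genes shown are above 0 in lymph node as well, while in tumor against mammary gland several are below 0, Plekha6 (-4.14), Scn4b (-3.91) and Ank3 (-2.42) the most.

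Genes higher in tumor were then followed in the other tissues. The set held the 1916 genes called at least 2-fold higher in tumor than in mammary gland, Gzmb and Havcr2 among them. Its median log2 fold change was 0.16 in blood (adjusted p = 0.000335, camera), 0.12 in spleen (adjusted p = 0.000242), 0.14 in lung (adjusted p = 0.000549) and 0.06 in lymph node (adjusted p = 0.00802), and 1195, 1193, 1170 and 1117 members were above 0. With the correlation estimated the adjusted p was 0.566 in each tissue. In the 24 libraries, with the correlation estimated, it was 0.00922 in blood and in spleen, 0.0098 in lung and 0.0719 in lymph node. The set was chosen on tumor libraries that share dates with those of the other tissues, and whether they share mice is not stated. The comparison that defined it had a mean pan-T level of 67.2% in tumor and 12% in mammary gland. With pan-T scaling 126 genes were called higher there. The set can therefore mark T cell content and is not taken as a program of tumor Tregs. Whether a larger share of FOXP3 cells shifted it in the other tissues was not tested. Without the lymph node library of WT replicate 3 the adjusted p was 0.0843, and without that of KEP replicate 3 it was 0.0552.

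Whether the KEP effect differs among blood, spleen, lung and lymph node was tested by an F test of the effects. Without pairing the edgeR test called 0 genes, with 544 at an unadjusted p under 0.05, 16 by DESeq2 and 39 in the 24 libraries. Among genes that met the naming rule the smallest p belonged to Nat10, Rhbdf2 and Socs3 (each adjusted p = 0.504); Pusl1, which overlaps Cpsf3l, is uncertain, and Gcnt1, Nebl, Snhg12 and the ribosomal protein genes Rps7, Rpl35a and Rpl31 followed. In pairs of tissues 1 gene was called, the tubulin gene Tubg2 between blood and lung (adjusted p = 0.0389), named after its values were seen. With the date as a block, which pairs libraries of the same title date, 629 genes were called. Il9r, the IL-9 receptor gene, led them, with log2 fold changes of 0.66 in blood, 1.17 in spleen, 0.93 in lung and -0.22 in lymph node (adjusted p = 1.35e-06). Others were Gcnt1 (0.72, 1.47, 1.20 and 0.28), Tox, a transcription factor of chronically stimulated T cells (0.90, 0.50, 0.79 and 0.08), Foxp3 (0.78, 0.64, 0.51 and 0.20, adjusted p = 0.0128), Il2ra (0.95, 0.34, 0.79 and 0.38), Itgae (1.12, 2.08, 1.32 and 0.46) and the lymph node homing receptor gene Ccr7 (-1.50, -0.23, -0.74 and 0.09); these genes of the blocked fit were named after its result was seen. With the block, lymph node differed from blood in 743 genes, from lung in 509 and from spleen in 74, blood from spleen in 54, and spleen from lung in 38. Blood and lung differed in 0 genes with the block, by edgeR, and in 1 without it.

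Tissues were also compared within a genotype. The tumor and mammary gland libraries hold RNA of other cells, so the genes are not assigned to Tregs. Tumor libraries against KEP spleen libraries showed higher Maff and Fosl2, stress-responsive transcription factors (82.7 ± 22.1 against 1.02 ± 0.37 CPM and 1659 ± 163 against 25 ± 0.735 CPM), and higher Ets2 (3.48), Ifrd1 (3.94), Adam9, a metalloprotease (3.81), and Fbln2, a matrix protein (642 ± 263 against 0.081 ± 0.084 CPM). Lower were Dzip1 (-3.07), Wdr73 (-1.81), Entpd5 (-1.60) and Arpc5l (-1.27), with Dennd2d (-2.56) and Cnp (-1.85) uncertain as overlapping genes. WT mammary gland libraries against WT spleen libraries showed higher Maff (207 ± 15.9 against 1.21 ± 0.295 CPM), Errfi1, an inhibitor of growth factor receptors (6.30), Procr (8.56), Ets2 (3.97), Cep170b (3.58) and Gde1 (1.72). Lower were Tmem229b (-2.90), Tnfrsf22 (-2.39), Frmd8 (-1.95) and Actb, cytoskeletal actin (1518 ± 38.2 against 6841 ± 90.7 CPM), with Cnp (-2.23) and Kbtbd4 (-1.78) uncertain; scaled to the pan-T genes all 6 were higher, Actb by 2.08. The counts were 9356 for tumor against spleen (5413 higher and 3943 lower) and 11577 for mammary gland against spleen (6678 higher and 4899 lower), and the libraries did not overlap in 8391 and 10488 of them. With the date as a block, which pairs libraries of the same title date although the deviations of such tumor and spleen libraries correlated at only -0.0179 to 0.0012 across genes, tumor against spleen gave 5090 genes; with the libraries of this comparison alone it gave 6048. Scaled to the pan-T genes tumor against spleen gave 6136 genes, of which 94.7% were higher against 57.9%, with the median of all genes at 1.04 against 0.13, and mammary gland against spleen gave 99.3% higher against 57.7%, with that median at 4.44 against 0.20. Tumors were digested with collagenase and the labels state no digestion for spleen, which these comparisons do not separate from the tissue.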

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

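The tests of the share of FOXP3 cells, of macrophage RNA and of the part of the log2 fold change that lower genes kept, and the splits of the dates in the fit with a block, were chosen after the results were seen; the GC and length correction, the scaling to pan-T genes and the fit of 24 libraries were added after the data were seen.

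Among the 4 WT mammary gland libraries, replicate 2 stood far above the others in T cell transcripts. The gap to the nearest library over the range of the group was 0.851 for Il2ra, 0.864 for Ctla4, 0.894 for Ikzf2, 0.831 for Cd4, 0.831 for Cd3e and 0.839 for the sum of 10 pan-T genes, each above Dixon's 95% critical value for 4 samples. That made 6 of 12 quantities, where chance would mark about 1 in 20; the quantities are not independent, since they share the T cell content of a library. Il2ra stood at 545 CPM in replicate 2 and at 35.1 to 111 CPM in the others, and Foxp3, at 416.7 CPM against 18.7 to 93.5, lay below the critical value with 0.812.

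The KEP effect differed between tissues in several tests. Between blood and lung 1 gene, Tubg2, was called without a block and 0 with the date as a block. With the date as a block 629 genes differed among blood, spleen, lung and lymph node, 54 between blood and spleen, 743 between blood and lymph node, 38 between spleen and lung, 74 between spleen and lymph node and 509 between lung and lymph node. In 365 of the 629 genes the effect in lymph node was the nearest to 0. The same share over all genes was not computed, and lymph node had the fewest genes called between KEP and WT (2). The count is therefore not taken as particular to the 629 genes. In the 10 splits of the 6 dates the real split gave 629 genes with the block and the highest other gave 18, and without the block the real split and the highest other gave 0, as did all 10 splits; 10 splits are too few for a share under 0.05, and in 1 of them, the real one, as many genes were called with the block.

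Treg identity and activation genes were higher in tumor than in WT mammary gland. A trend with GC content or transcript length is argued against as the whole cause, since with the correction 11 of the 11 called identity genes and 18 of the 18 called activation genes were still called. A lower share of T cell RNA in the mammary gland libraries cannot be told apart from a change within Tregs: scaled to 10 pan-T genes, the median log2 fold change was 0.13 for the identity list (0.125 before rounding) and 0.34 (0.343) for the activation list. A difference between tumor and healthy tissue in the state of Tregs stays open. RNA of macrophages or other cells in the tumor libraries was not tested as a source of the identity and activation genes. Of 35 splits of the 7 libraries, 1, the real one, gave as many genes (8064, highest other 5667). That is the smallest share 35 splits can give, under 0.05, and argues against chance for the count without excluding it. As many lists were called in 13 splits (16, highest other 19), so chance is not excluded for the lists.

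In spleen, lung and blood 33 genes were higher in KEP mice, and GC content or length is argued against as the whole cause by 27 of 33 still called in all 3 tissues with the correction. RNA from macrophages or monocytes, which would raise their own genes at least as much, is argued against in lung. There their list had a median of -0.86 (-0.861, SE over members 0.273), and their summed CPM changed by -1.16 on the log2 scale (SE over libraries 0.329). It is also argued against in blood, with a median of 0 (SE over members 0.456) beside a median of 1.06 for the 33 genes. The sum there was 76.3 ± 18.9 against 68.8 ± 6.8 CPM (log2 fold change 0.149, SE over libraries 0.222). The SE over members takes genes that vary together as independent and is too small, so the sums carry the argument. In spleen RNA of these cells stays open, with a median of 1.12 (1.116, SE over members 0.304) beside 1.14, although the sum, 53.6 ± 14.2 against 37.9 ± 3.5 CPM, rose by less. Other cells were not weighed in this way. The list of 10 neutrophil genes had medians of 6.54 in spleen, 2.51 in lung and 3.59 in blood. Of its genes 9, 10 and 9 were above 0, with 0 called over all genes in each tissue. RNA of neutrophils was not tested as a source of the 33 genes and stays open in all 3 tissues. A larger share of FOXP3 cells stays open too: the set's median lay above the log2 fold change of Foxp3 by at least 2.65 SE in the 24 libraries and by 0.46 to 0.93 SE in the fit of all libraries, but the genes were chosen for being higher, so this excludes nothing. The title date, which no KEP and WT library shared, and the genotype cannot be told apart, and a systemic effect of the tumor stays an untested hypothesis. Of 10 splits of the dates 1, the real one, gave as many genes called in 3 tissues (33, highest other 0), and 10 splits are too few for a share under 0.05.

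Genes lower in KEP lung and blood were richer in GC. With the GC and length correction 104 of 216 lower genes in lung and 212 of 325 in blood were still called, and 145 and 283 kept at least 75% of their log2 fold change; the median went from -0.62 to -0.51 in lung (median SE 0.143 to 0.136) and from -0.73 to -0.67 in blood (median SE 0.171 to 0.166), so calls ended as the effects shrank. This argues against GC as the whole cause in blood, while in lung GC bias cannot be told apart from expression, since over 1 in 4 genes lost more of their effect. The number of sorted cells is argued against in lung, where 201 of 216 were still called. In blood 137 of 325 were still called and 319 kept at least 75% of their log2 fold change. Their median was -0.75 after -0.73 and their median SE 0.19 after 0.171, so calls ended as the spread grew. The fit held 1 slope for all 31 libraries, and KEP blood libraries mostly had more cells than WT ones. It therefore cannot decide on cell number in blood. A biological difference between genotypes stays open as untested.

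For comparisons of 3 libraries with 3, 10 splits are too few for a share under 0.05. The real split and the highest other gave 2 and 0 genes in lymph node, 68 and 0 in spleen, 469 and 0 in lung, 657 and 17 in blood, and 9356 and 857 in tumor against spleen, each with 1 split as large. For gene lists adjusted within a comparison they gave 7 and 12 in lymph node (5 splits as large), 10 and 14 in spleen (3 splits), 5 and 8 in lung (6 splits) and 3 and 8 in blood (9 splits). For the absolute median of the tumor gene set they gave 0.057 and 0.058 in lymph node (2 splits), 0.123 and 0.084 in spleen, 0.137 and 0.061 in lung, and 0.16 and 0.089 in blood (1 split each). For mammary gland against spleen, 1 of 35 splits, the real one, gave as many genes (11577, highest other 7639). That is the smallest share 35 splits can give, and argues against chance without excluding it.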

How the results depend on the processing

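The GC and length correction, the 24-library fits, the scaling to pan-T genes, WT mammary gland replicate 2 as the control and the block together with GC were chosen after the data were seen; where no reason is given, the cause was not tested. Named genes had 350 results and 6296 values under alternatives, of which 5733 kept their direction and side of the threshold, 336 were weaker, 162 stronger and 46 reversed, and 19 changed sign without a call. No filter on low counts gave 264 genes in lung and 382 in blood; WT mammary gland replicate 2 as the control, picked for its T cell RNA and assumed to vary like the other groups, gave 4549 genes in tumor against mammary gland, where cell number gave 4983; cell number gave 293 in blood; GC gave 6 in lymph node and 309 in lung. The 24 libraries gave 2591 in blood, 546 in spleen, 2550 in lung and 143 in lymph node, and only the libraries compared gave 3667 in tumor against mammary gland, 193 in lymph node, 589 in spleen, 1599 in lung, 1688 in blood, 6048 in tumor against spleen and 39 for the test of differing effects. DESeq2 gave 37 in lymph node, 174 in spleen, 956 in lung, 1064 in blood and 16 for differing effects; limma-voom gave 1 in lymph node and 45 in spleen, and 5 in lymph node with the date as a random block. A minimum change of 2-fold, stricter by construction, gave 4693 in tumor against mammary gland, 1 in lymph node, 42 in spleen, 85 in lung, 197 in blood, 5618 in tumor against spleen and 7602 in mammary gland against spleen. The date as a block gave 629 genes for differing effects (720 with GC) and 5090 for tumor against spleen. With it all 10 genes named for the test of differing effects were called, from Gcnt1 (adjusted p = 7.63e-05) to Rpl35a (adjusted p = 0.0328). As a random term in limma-voom the block ended the call of Bnip3 in blood (1.06, adjusted p = 0.0521, against 0.0484 by limma-voom without it), and the block changed no other call of a named gene. List tests called numbered 0 of 145 with an estimated correlation, against 49, and 9 of 116 in the 24 libraries. With an estimated correlation the tumor gene set had medians of 0.16 in blood, 0.123 in spleen, 0.137 in lung and 0.057 in lymph node (each adjusted p = 0.566), and in lymph node 0.064 (adjusted p = 0.0719) in the 24 libraries.

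Leaving out 1 library gave 6925 to 8784 genes in tumor against mammary gland, 1 to 5 in lymph node, 25 to 63 in spleen, 40 to 413 in lung, 155 to 489 in blood, 8092 to 9752 in tumor against spleen, 10995 to 11692 in mammary gland against spleen and 0 for differing effects by edgeR, where 544 genes had an unadjusted p under 0.05 with all libraries and DESeq2 called 16. The tumor set's median ranged from 0.035 (without KEP lymph node replicate 3, adjusted p = 0.0552) to 0.088 in lymph node, 0.073 to 0.137 in spleen, 0.108 to 0.147 in lung and 0.137 to 0.187 in blood.

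Scaling to pan-T genes gave 14132 genes in tumor against mammary gland and 6136 in tumor against spleen, with medians of all genes of -3.43 after -0.10 and 1.04 after 0.13; RLE factors gave 0.24 after 0.13 in tumor against spleen and 0.32 after 0.20 in mammary gland against spleen, and GC -0.22 after -0.10 in tumor against mammary gland. By its construction the pan-T scaling lowers other genes where T cell RNA is scarcer in the control. It reversed these log2 fold changes of named genes in tumor against mammary gland: Pgk1 -1.33, Arl5a -0.49, Capza1 -2.01, Apaf1 -2.10, Mov10 -1.31, Capg -1.17, Ikzf4 -1.44, Prdm1 -0.96, Id2 -0.20, Cd44 -0.47, Lgals1 -0.21, Fgl2 -1.28, Lef1 -0.42, Nfil3 -2.13, Batf -0.38, Tk1 -2.04, Trim30a -1.14, Gbp7 -1.88, Cd274 -0.84, Gbp3 -1.19, Nfkbie -1.60, Tnip1 -1.90, Ccnd2 -1.28, Rel -0.51, Pkm -1.88, Hif1a -1.32, Dhcr7 -2.45, Sdhb -2.98, Csf2 -0.21, Tbx21 -0.33, Cd79b -0.74, Ighm -0.56, Aif1 -0.09, Cd74 -1.11, Zbtb46 -1.52, Itgax -0.23, Prf1 -0.63, Col1a1 -0.29, Napsa -0.35 and Cd4 -0.025. In mammary gland against spleen it reversed Kbtbd4 2.43, Cnp 1.92, Frmd8 2.20, Actb 2.08, Tmem229b 1.23 and Tnfrsf22 1.67.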

Other observations

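The observations on ribosomal protein genes and on Klrb1c were chosen after the results were seen.

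Transcripts of 81 ribosomal protein genes, which encode the protein parts of the ribosome, took 3.31 ± 0.13% of counts in KEP blood against 4.37 ± 0.54% in WT blood (SD, n = 3 each) and 3.56 ± 0.24% in KEP lung against 4.53 ± 0.49% in WT lung. In spleen the shares were 4.56 ± 0.32% against 4.86 ± 0.33%, and in lymph node 5.19 ± 0.28% against 4.63 ± 0.14%. The median log2 fold change was -0.40 in blood, with 23 genes called lower and 79 below 0, -0.37 in lung, with 13 called lower and 79 below 0, -0.10 in spleen and 0.16 in lymph node. The signs of these medians held with RLE and upper-quartile factors, cell number, DESeq2 and the 24 libraries. With the GC and length correction they were -0.34, -0.32, -0.17 and 0.04, with 35 genes below 0 in lymph node. With the date as a block 56 of the 80 genes tested were among the 629 of 12825 whose KEP effect differed among tissues, where 3.9 would be expected by size of the group. That number takes the genes as independent, and the group was chosen after some members had appeared among the leading genes for differing effects. The excess is therefore not a test.

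Klrb1c, an NK cell receptor gene, was lower in KEP blood, at 21.9 ± 16.2 against 74.6 ± 24.1 CPM (SD, n = 3 each). Its log2 fold change was also below 0 in lymph node (-1.70), lung (-1.40) and spleen (-1.02), where it was not called. In blood it was not called with the number of sorted cells in the model (-1.79, adjusted p = 0.0622), without a filter on low counts (-1.78, adjusted p = 0.0693), with the blood libraries alone (-1.78, adjusted p = 0.139), or without WT replicate 1 or 3 or KEP replicate 1 or 3 (adjusted p = 0.087, 0.115, 0.163 and 0.173).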
